A study of Mus musculus with 12 samples.

How the data were processed

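The series holds bulk paired-end RNA sequencing of spinal cord lesions from 12 female mice in 3 groups of 4 (SCI7, OVX2_SCI7 and OVX8_SCI7). The groups and replicate numbers were taken from the sample labels, which describe the samples as biological replicates and give 1 batch for all. The library kit, the RNA selection, the read length and whether strand was used in counting were not given in the sources used here.

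Per the submitters' processing notes, reads were trimmed with fastp 0.23.4, aligned to GRCm39 with HISAT2 2.2.1 and quantified with RSEM 1.3.3, and the notes also name DESeq2 1.42.0, edgeR and limma. The authors deposited 3 tables of 57180 genes, with an identifier, a symbol and 1 column per sample. The first holds expected counts, estimated counts that the authors obtained with RSEM and that need not be whole, and they were rounded to whole numbers here. The second holds TPM, transcripts-per-million values deposited by the authors, and the third holds FPKM, fragments per kilobase scaled to library size, also deposited by the authors. Each table has 3 value columns whose names match no sample analysed here, 9 in all, and they were not used. The 525 genes with an identifier and no symbol held 0.0786 to 0.158% of the counts of a library and stayed in library sizes and tests. Columns were checked across tables by name. Over 9014 genes, log deviations of the counts from each gene's mean correlated at 0.920 to 0.974 with those of TPM and FPKM under the same sample name, and at most 0.852 with any other sample. No 2 libraries of a group differed as little as sampling noise, since the chi-square per gene was 13.1 to 394.

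Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with the group as its argument, which left 17821, and scaled by TMM. All 12 libraries entered 1 fit with the group as the only term, so that the comparisons share an estimate of the spread (common biological coefficient of variation 0.312). Each comparison and the joint test of the 3 groups used the robust quasi-likelihood F-test with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Counts-per-million values (CPM) were computed from the rounded deposited counts and the TMM-scaled library sizes. Those of Esr2, of the sensory neuron transcripts and of the floor of 3 counts used the library totals without this scaling. The log2 fold changes are those of the edgeR fit to the deposited counts. Fixed lists of marker and pathway genes, 52 in all (21 cell types and 31 pathways), were tested with limma camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 50 lists that had at least 3 tested members. Camera asks whether a list's genes lie higher or lower than the other genes. The fry test of limma asks whether they move on balance in 1 direction.

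The groups, the tests, the gene lists, the rule for named genes and a first set of other settings were fixed before the data were examined. The rule names, for each comparison, the 10 genes with the largest change in each direction among those that passed, with a mean of at least 1 CPM and no overlap between the libraries of both groups. Predicted genes, pseudogenes and entries without a symbol are skipped, and where fewer than 5 genes pass, the 10 genes with the smallest p are given as values. It adds the 4 members with the smallest p of each called list, the 2 with the smallest p of each other list described, and 11 fixed genes of the hormone axis and the injury response. The rule also picked 4 genes that are not reported here. They were left out of the named genes after the data were seen, without replacement, and stay in every test over all genes or lists. Genes outside the rule are marked in the text as chosen after their values were seen.

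The other settings fixed then were DESeq2 size factors in place of TMM, no low-count filter, a stricter filter (at least 1 CPM in 4 libraries and a mean of 50 counts), DESeq2 1.42.0, limma-voom with and without quality weights, limma-trend on log2(TPM + 1), a minimum log2 fold change of 1, the 8 libraries of a comparison alone, the replicate number as a block, and leaving out each library in turn. For the lists they were an estimated correlation, fry and the same changes of scaling, filter and samples. After the data were seen, these were added: an offset for each library's trend on GC content and length, alone and with DESeq2, with the block or without replicates 1 and 2 of OVX2_SCI7; protein-coding nuclear genes only; and leaving out those replicates without the offset. The offset is a natural spline with 5 degrees of freedom of each library's log2 CPM deviation on the GC content and log length of a gene, fitted over genes with a mean of at least 5 CPM. GC content and length came from the longest protein-coding transcript of the gene in the mouse annotation at hand, which is of an older build than the one the authors used, or the longest transcript where none codes. Genes were matched by identifier, 97.91% of tested genes had a value, and no coordinates are given because the builds differ.

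Comparisons of a single library measure used exact two-sided permutation tests. Scripts were tested on simulated counts for 17821 genes with 100 genes changed 2-fold and 100 changed 4-fold. In data without a GC trend, edgeR recovered 38%, 37% and 43% of the genes changed by 1 on the log2 scale and 89%, 89% and 86% of those changed by 2, for OVX2_SCI7 against SCI7, OVX8_SCI7 against SCI7 and OVX8_SCI7 against OVX2_SCI7. Its false calls were 6.62%, 5.26% and 2.27% of all calls in the same order. With a simulated GC trend added to every library of a group they were 75.2%, 78.9% and 78.3%, and with the offset 1.55%, 3.79% and 0.752%. For OVX2_SCI7 against SCI7, DESeq2 recovered 61% and 94% of the changed genes without a GC trend, and 23.65% of its calls were false, or 90.85% with a GC trend, so its counts are read with that error. A list shifted in the simulation was called by camera in all 3 comparisons, with 0 other lists called. Genes were drawn independently there, so this does not test camera where list members correlate. In the data the estimated correlation was 0.952 for cell division genes in OVX8_SCI7 against SCI7. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.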

Results

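Spinal cord tissue from female C57BL/6J mice was sequenced 7 days after a clip compression injury, taking the lesion and about 0.5 cm of cord on each side of it. The 12 libraries form 3 groups of 4, described by the labels as biological replicates. SCI7 mice had the injury alone, OVX2_SCI7 mice had their ovaries removed 2 weeks before the injury, and OVX8_SCI7 mice 8 weeks before it. Ovariectomy removes the main source of circulating oestrogen and is widely used to cause bone loss in rodents, and the series title places a model of spinal cord injury with osteoporosis beside the plain injury. No uninjured cord and no sham operation was analysed here, so surgery, hormone loss and the time since surgery differ together between the groups. All labels give an age of 8 weeks, and the time point it refers to was not given in the sources used here. For OVX8_SCI7 it cannot be the age at collection, which came 7 days after an injury made 8 weeks after ovariectomy. If it is the age at ovariectomy, the age at injury also differs between OVX2_SCI7 and OVX8_SCI7. SCI7 mice had no ovariectomy and carry the same label, so whether their age at injury differed from that of either ovariectomy group is not known. Age may therefore differ between the groups along with surgery, hormone loss and the time since surgery.

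Genes of glia were abundant in every group. Gfap, a filament protein of astrocytes, stood at 5312 ± 354 CPM (counts-per-million, mean ± SD, n = 4) in SCI7, 6189 ± 1700 in OVX2_SCI7 and 6262 ± 629 in OVX8_SCI7. Mbp, the myelin basic protein of oligodendrocytes, stood at 9730.4 ± 1077, 12964 ± 3978 and 12124 ± 1837 CPM in the same order. The oestrogen receptor gene Esr1 was low at 9.39 ± 3.13, 7.22 ± 1.05 and 7.96 ± 1.47 CPM, and Esr2 was under the low-count filter at 0 to 0.491 CPM per library. Xist, the transcript of the inactive X chromosome, was high in every library, with a group mean of 705 CPM or more. Library totals ran from 18222809 to 31781728 counts, with means of 19248357 ± 957349.6 in SCI7, 19555991 ± 548162 in OVX2_SCI7 and 23070660.0 ± 6082834 in OVX8_SCI7. A floor of 3 counts equals 0.0944 to 0.165 CPM, and floors cover counting error only.

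The libraries also differed in measures that follow the groups. Transcripts encoded by the mitochondrial genome took 7.63 ± 1.80% of counts in SCI7, 4.17 ± 2.80% in OVX2_SCI7 and 2.79 ± 0.515% in OVX8_SCI7. In OVX2_SCI7 the share was 8.33% in replicate 1 and 2.36 to 3.13% in the other libraries. In each library, the level of protein-coding genes relative to the mean of the 12 libraries followed the GC content of their transcripts. The Spearman correlation across genes was -0.68 ± 0.16 in SCI7, 0.25 ± 0.46 in OVX2_SCI7 and 0.62 ± 0.31 in OVX8_SCI7, and replicate 1 of OVX2_SCI7 was at -0.44. Genes are not independent replicates, so this correlation describes a library. All 8 libraries from ovariectomised mice lay above the 4 SCI7 libraries, replicate 1 of OVX2_SCI7 by a small margin, since the highest SCI7 library was at -0.53. The exact two-sided permutation p was 0.0286 for OVX8_SCI7 against SCI7 in both measures, the smallest that 4 against 4 libraries allow, and 0.0857 after Benjamini-Hochberg adjustment over 12 tests. For OVX2_SCI7 against SCI7 it was 0.0286 for the GC trend and 0.0857 for the mitochondrial share (adjusted 0.0857 and 0.206). Replicate 2 of OVX2_SCI7 held sensory neuron transcripts, with Pirt, a gene chosen after its values were seen, at 135 CPM against 0.177 to 21.6 in the other libraries.

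**Figure D1:**
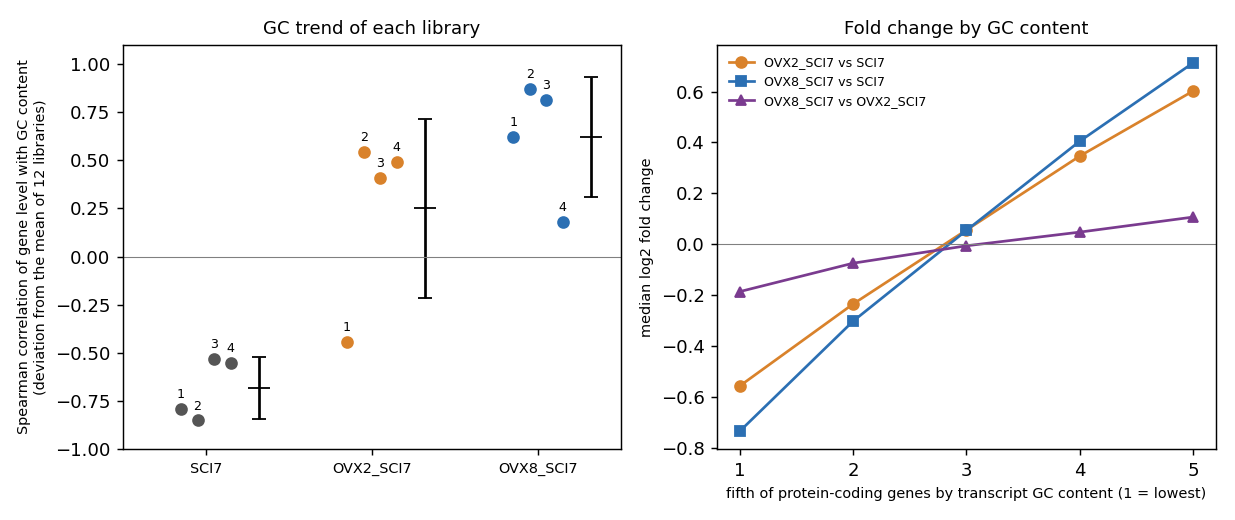
Left, the Spearman correlation across genes between a gene's level in a library, relative to the 12-library mean, and the GC content of its transcript, 1 point per library with the group mean ± SD. Right, the median log2 fold change in each quintile of 15087 protein-coding genes ordered by GC content, running from -0.74 to 0.71 for OVX8_SCI7 against SCI7.

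The first comparison asks how ovariectomy 2 weeks before the injury altered the lesion transcriptome. No gene passed the threshold, and the 10 genes with the smallest p-values are given as values. Oas2, an antiviral enzyme induced by interferon, stood at 8.72 ± 1.59 CPM (SD, n = 4) in OVX2_SCI7 and 2.57 ± 0.482 in SCI7, a log2 difference of 1.76 (SE 0.23). Irf7, a transcription factor that amplifies the interferon response, stood at 27.0 ± 6.01 against 9.19 ± 2.10 CPM (1.55, SE 0.25). The class I genes H2-Q6, H2-Q7 and H2-Q4 had log2 differences of 2.09 (SE 0.28), 2.05 (SE 0.29) and 1.66 (SE 0.26), which are uncertain because these near-identical genes share reads. Lgals3bp, a secreted galectin-binding protein, stood at 263 ± 81.2 against 80.8 ± 21.1 CPM, and Slamf8, a receptor of myeloid cells, at 2.74 ± 0.920 against 0.597 ± 0.166 CPM. Cd8a, the co-receptor of cytotoxic T cells, stood at 0.910 ± 0.216 CPM against 0.0527 ± 0.0432, which is under the floor, so no fold is given, and Ikzf3, a lymphocyte transcription factor, at 0.904 ± 0.105 against 0.172 ± 0.1005 CPM. Bcl2l1, which protects cells from apoptosis, stood at 119 ± 13.7 against 70.6 ± 6.13 CPM. All 4 OVX2_SCI7 libraries lay above all 4 SCI7 libraries for each of these 10 genes. Chance gives full separation, in either direction, in 1 of 35 splits of 8 libraries for a gene taken at random. That share does not apply to genes picked for a small p.

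The quasi-likelihood test of edgeR called 0 of 17821 genes, with a smallest Benjamini-Hochberg adjusted p of 0.052, while 5789 genes had an unadjusted p under 0.05. DESeq2 called 3579 genes, limma-voom 705, limma-voom with quality weights 9679 and limma-trend on TPM 16. The count moved with the low-count filter, to 14 genes with none and 1148 with a stricter one, and fitting the 8 libraries alone gave 2. It rested on single libraries, since edgeR called 6264 genes without replicate 1 of OVX2_SCI7, 4 without replicate 1 of OVX8_SCI7 and 1 without replicate 4 of SCI7. With an offset for each library's trend on GC content and transcript length, chosen after the data were seen, edgeR called 8 genes, all higher: Oas2, Gbp3, Lgals3bp, H2-Q4, H2-Q6, Xaf1, Cd8a and Ifi27, with log2 differences of 0.71 for Ifi27 to 1.72 for H2-Q6 and no fold given for Cd8a, whose SCI7 mean is under the floor. Gbp3, Xaf1 and Ifi27, interferon-induced genes outside the rule for named genes, were chosen after their values were seen. Leaving out replicates 1 and 2 of OVX2_SCI7, also chosen after the data were seen, gave 7139 genes.

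Among the gene lists fixed beforehand, 7 of 50 were called by limma camera in OVX2_SCI7 against SCI7, and no member of any of them passed over all genes tested. The type I interferon list had a median log2 difference of 0.87 over 18 members (camera adjusted p = 6.2e-09), and 14 members were higher when adjusted over the list alone. Its members include Oasl2, at 48.9 ± 5.87 against 23.3 ± 6.11 CPM, Oas1a, at 16.9 ± 7.23 against 5.32 ± 1.55, and Zbp1, a sensor of nucleic acids, at 9.10 ± 4.36 against 2.90 ± 0.742. The antigen presentation list had a median of 1.59 over 13 members (camera adjusted p = 2.9e-07), 12 of them higher when adjusted over the list alone. H2-K1, a classical class I gene, stood at 345 ± 188 against 94.4 ± 26.9 CPM, and H2-Ab1, a class II gene, at 48.7 ± 30.8 against 13.9 ± 6.90. Tap1, a subunit of the peptide transporter, stood at 36.1 ± 20.3 against 12.5 ± 4.83 CPM. The complement list had a median of 0.93 over 12 members (camera adjusted p = 0.0369), 6 of them higher when adjusted over the list alone. C3, the central component of the cascade, stood at 270 ± 77.4 against 164 ± 21.7 CPM and C4b at 479 ± 82.3 against 317 ± 38.7. With an estimated correlation the camera adjusted p was 0.863 for the interferon list and 0.988 for both others, and across the 23 alternatives run the interferon value ran from 3.5e-21 to 0.863.

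Markers of ependymal cells, the ciliated lining of the central canal, had a median log2 difference of 0.79 over 8 members (camera adjusted p = 0.0182). Adjusted over the list alone 3 were higher, namely Foxj1, the regulator of motile cilia (0.84, SE 0.21), Rarres2 (0.91, SE 0.26) and Ccdc153 (1.05, SE 0.33). Glucocorticoid-responsive genes had a median of 0.31 over 11 members (camera adjusted p = 0.0359), with 5 higher when adjusted over the list alone: Zbtb16, Fkbp5, Mt1, Mt2 and Cdkn1a. Zbtb16 stood at 26.9 ± 9.72 against 8.63 ± 2.47 CPM, and Fkbp5, a brake on the glucocorticoid receptor, at 92.7 ± 63.1 against 39.7 ± 9.54. Ribosomal protein genes had a median of 0.78 over 22 members (camera adjusted p = 0.0141). Adjusted over the list alone, Rpl13, Rpl27, Rpl37, Rps15 and Rps6 were higher and Rpl5 lower (log2 difference -0.77, SE 0.17), and values of this family are uncertain because its pseudogenes share reads. Mitochondrially encoded transcripts had a median of -0.95 over 13 members (camera adjusted p = 0.000435), and mt-Atp8 alone was lower when adjusted over the list alone, at 101 ± 51.8 against 314 ± 191 CPM. The camera adjusted p with an estimated correlation was 0.863 for the ependymal and glucocorticoid lists and 0.988 for the ribosomal and mitochondrial lists.

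The directional fry test of limma called 3 of these lists, the interferon, ependymal and glucocorticoid lists, at an adjusted p of 0.0222 each. Leaving out 1 library ended 4 of the camera calls. The complement value became 0.0583 without replicate 1 of SCI7, 0.138 without replicate 3 of SCI7, and 0.0766 and 0.0927 without replicates 3 and 4 of OVX2_SCI7. The ependymal value became 0.0538 without replicate 4 of SCI7 and 0.130 without replicate 1 of OVX2_SCI7, and the glucocorticoid value 0.0583 and 0.0694 without replicates 1 and 4 of SCI7 and 0.159 without replicate 1 of OVX2_SCI7. The ribosomal value became 0.0841 without replicate 3 of SCI7, and 0.225 and 0.0653 without replicates 3 and 4 of OVX2_SCI7. The interferon, antigen presentation and mitochondrial lists were called in 12 of 12 such fits, and 11 lists were called without replicate 2 of OVX2_SCI7. Fold changes of this comparison followed transcript GC content, with a Spearman correlation of 0.788 across 15087 protein-coding genes, which are not independent. With the GC and length trend removed camera called all 7 among 15 lists, but 0 with an estimated correlation (smallest adjusted p 0.174). Of the 3 lists that fry had called, it then called the interferon list (adjusted p = 0.00707) and not the ependymal and glucocorticoid lists (0.174 each), and it called T and NK cells (0.0122), which is not among the 7. The medians of the 7 were then 1.03 for interferon, 1.08 for antigen presentation, 0.49 for complement, 0.44 for ependymal cells, 0.26 for glucocorticoid-responsive genes, 0.29 for ribosomal proteins and -0.30 for mitochondrial transcripts, which have a median GC content of 37.1%.

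**Figure D2:**
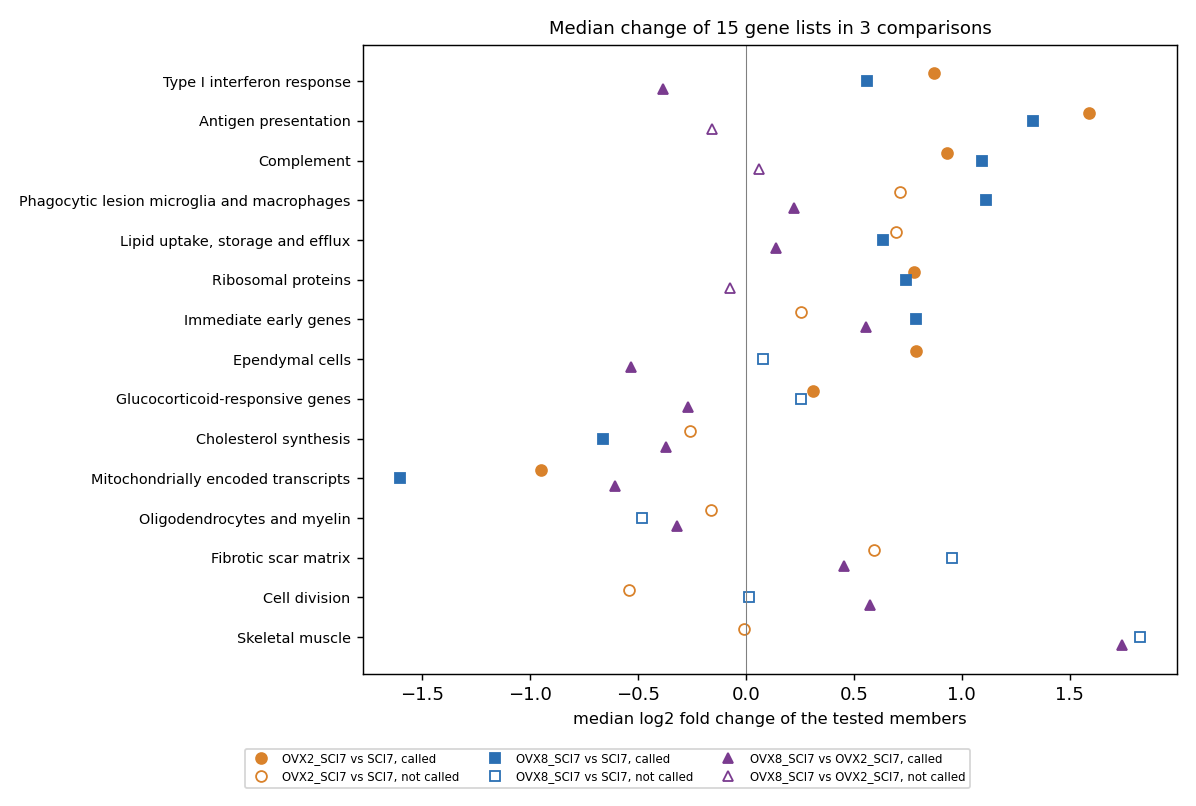
Median log2 fold change of the tested members of 15 gene lists in the 3 comparisons, with filled points where limma camera called the list. The interferon median is 0.87 for OVX2_SCI7 against SCI7, 0.56 for OVX8_SCI7 against SCI7 and -0.38 for OVX8_SCI7 against OVX2_SCI7.

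The second comparison asks the same of ovariectomy 8 weeks before the injury. In OVX8_SCI7 against SCI7, 2113 genes rose and 2781 fell of 17821 tested. Plin4, a coat protein of lipid droplets, rose from 11.1 ± 4.84 to 52.5 ± 14.1 CPM (log2 fold change 2.24, SE 0.30, n = 4 per group), and Alox15, a lipoxygenase that makes lipid mediators, from 0.486 ± 0.121 to 1.94 ± 0.604 CPM (1.98, SE 0.40). Slamf8 rose by 2.06 (SE 0.33), Kcnn4, a calcium-activated potassium channel of immune cells, by 2.18 (SE 0.72), Crlf2, a cytokine receptor chain, by 2.03 (SE 0.53) and Cilp2, a cartilage matrix protein, by 2.31 (SE 0.72). Actn3, an actinin of fast skeletal muscle, rose by 2.01 (SE 0.47), and the muscle myosin Myh4 stood at 5.82 ± 7.13 against 0.459 ± 0.470 CPM. AKAP17A and Rsc1a1 rose by 2.10 (SE 0.46) and 1.98 (SE 0.67), both uncertain because they overlap or resemble other genes. Each of these 9 genes, not counting Myh4, was higher in 4 of 4 OVX8_SCI7 libraries than in every SCI7 library, as the rule that names them requires.

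The largest decreases in OVX8_SCI7 were in genes of mixed kinds. Septin2, a cytoskeletal filament protein, fell from 231 ± 63.8 to 56.0 ± 20.5 CPM (log2 fold change -2.04, SE 0.36) and mt-Nd3, a subunit of respiratory complex I, from 129 ± 57.6 to 30.2 ± 14.95 CPM (-2.10, SE 0.53). Sycp3, a protein of meiotic chromosomes, fell by 3.12 (SE 0.74). H3c14 stood at 0.108 ± 0.216 against 6.94 ± 3.65 CPM and Snurf at 0.117 ± 0.135 against 4.17 ± 2.39 CPM, with OVX8_SCI7 means about at the floor, so that their fitted folds are no bounds. Rpl37rt fell by 3.95 (SE 0.72), Or8b48 by 2.07, and the antisense transcripts Hoxb3os and Phtf1os by 2.30 (SE 0.35) and 2.00 (SE 0.45). H3c14, Snurf, Rpl37rt, Or8b48 and the antisense transcripts are uncertain, because they overlap or copy other genes and the strand used in counting was not given in the sources used here. All 9 were lower in 4 of 4 OVX8_SCI7 libraries than in every SCI7 library, by the same rule.

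These 18 genes had adjusted p between 0.0143 and 0.0458 in the quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment, which called 4894 genes in all. DESeq2 called 6313, limma-voom 4881, limma-voom with quality weights 11212 and limma-trend on TPM 2878, and leaving out replicates 1 and 2 of OVX2_SCI7, chosen after the data were seen, gave 7720. Fold changes followed the GC content of the transcripts, with a Spearman correlation of 0.818 across 15087 protein-coding genes, which are not independent. In the quintile of genes with the lowest GC content 57.4% were called lower, and in the highest quintile 43.0% were called higher. With an offset for GC content and transcript length, chosen after the data were seen, edgeR called 0 genes, with 2734 at an unadjusted p under 0.05 and 824 called by DESeq2 under the same offset. The median log2 fold change of the genes called higher went from 0.79 (median SE 0.21) to 0.12 (0.14) under the offset and that of the genes called lower from -0.85 (0.21) to -0.24 (0.15), while Plin4 was at 1.70 (edgeR quasi-likelihood with Benjamini-Hochberg adjustment, adjusted p = 0.0903).

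The calls also rested on single libraries. The quasi-likelihood test of edgeR called 0 genes without replicate 2 of OVX8_SCI7, the library with 31781728 counts. It called 2349, 1641 and 2910.0 without replicates 1, 2 and 3 of SCI7, and 2538 and 1215 without replicates 1 and 3 of OVX8_SCI7. The named genes include 94 that passed in this comparison, and leaving out replicates 1, 2, 3 and 4 of SCI7 ended the calls of 48, 56, 40 and 9 of them. Leaving out replicates 1, 2, 3 and 4 of OVX8_SCI7 ended 40, 94, 70 and 13 of these calls, and leaving out replicates 1, 2, 3 and 4 of OVX2_SCI7 ended 0, 3, 0 and 9, with no change of sign in any of these fits.

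In this comparison limma camera called 9 of 50 gene lists, of which 1 is a list of microglia and macrophages. The list of phagocytic lesion microglia and macrophages had a median log2 fold change of 1.11 over 16 members (camera adjusted p = 0.00735). Apoe, a lipid carrier, rose from 3403 ± 1186 to 11575 ± 1805 CPM and Trem2, a lipid-sensing receptor of microglia, from 92.0 ± 44.5 to 290.0 ± 60.0 CPM. These 2 passed over all genes and 0 passed when adjusted over the list alone. Homeostatic microglia, with a median of 0.06 (camera adjusted p = 0.681), and monocytes and macrophages, with one of -0.04 (camera adjusted p = 0.806), were not called. The list of lipid uptake, storage and efflux had a median of 0.64 over 15 members (camera adjusted p = 0.0393), with Apoe and Nr1h3, an oxysterol receptor, higher (Nr1h3 1.28, SE 0.38), also when adjusted over the list alone. Cholesterol synthesis had a median of -0.66 over 21 members (camera adjusted p = 0.0412), and 8 of its genes fell, as did 8 when adjusted over the list alone. Idi1, an isomerase of the pathway, fell from 103 ± 32.5 to 31.7 ± 3.08 CPM and Hmgcs1, an early enzyme of it, from 352 ± 89.9 to 149 ± 7.31 CPM, and Msmo1 fell by 1.31 (SE 0.33). For these 3 lists and the 6 others called here, the camera adjusted p was 0.970 with an estimated correlation.

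The antigen presentation, interferon and complement lists were also called higher by camera, each with part of its members passing over all genes, and none of the 3 was called with an estimated correlation. In the antigen presentation list, with a median of 1.33 over 13 members (camera adjusted p = 2.3e-05), 8 members rose, and 12 when adjusted over the list alone. H2-K1 rose from 94.4 ± 26.9 to 280 ± 49.5 CPM, H2-D1 by 1.54 (SE 0.40), and H2-Ab1 from 13.9 ± 6.90 to 47.9 ± 4.38 CPM. In the interferon list, with a median of 0.56 over 18 members (camera adjusted p = 0.00921), 8 members rose and 1 fell, and 9 and 1 did when adjusted over the list alone. Oas1a rose by 1.44 (SE 0.31), Irf7 by 0.98 (SE 0.25) and Zbp1 by 1.16 (SE 0.33), whereas Ifit2 fell by 0.51, a gene chosen after its values were seen. In the complement list, with a median of 1.09 over 12 members (camera adjusted p = 0.0159), C4b, C1qa and C1qb rose, and 6 members did when adjusted over the list alone. C1qb, a recognition chain made by microglia, rose from 260 ± 115 to 714 ± 70.2 CPM. With an estimated correlation the camera adjusted p of these 3 lists was 0.970, and across the 23 alternatives run the antigen presentation value ran from 5.3e-09 to 0.970. SCI7 replicate 3 had the lowest score of the 4 SCI7 libraries on the antigen presentation and phagocytic lists.

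Mitochondrially encoded transcripts showed the largest median of the 9 called lists, at -1.60 over 13 members (camera adjusted p = 1.7e-05), and 11 fell, as did 11 when adjusted over the list alone. mt-Atp6, a subunit of ATP synthase, fell from 705 ± 351 to 233 ± 38.6 CPM and mt-Nd4l, of complex I, from 99.1 ± 13.6 to 27.3 ± 13 CPM. The list's transcripts have a median GC content of 37.1%, and its median was -0.42 with the GC and length trend removed (camera adjusted p = 0.0274). Ribosomal protein genes had a median of 0.74 over 22 members (camera adjusted p = 0.0225), with Rps6, Rpl13 and Rpl27 higher and Rpl5 lower, and 1 higher and 1 lower when adjusted over the list alone. All genes with a symbol that starts with Rpl or Rps and a digit, a wider set than this list, took 1.63 ± 0.369% of counts in OVX8_SCI7 and 1.05 ± 0.216% in SCI7. Immediate early genes had a median of 0.79 over 12 members (camera adjusted p = 0.0258). Ier2 rose by 1.67 (SE 0.54) in this list, and 0 members passed when adjusted over the list alone. With an estimated correlation the camera adjusted p was 0.970 for these 3 lists as well, and fry called 0 of 50 lists, with a smallest adjusted p of 0.0645.

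With the GC and length trend removed, camera called 16 lists, 8 of them among these 9, but 0 with an estimated correlation (smallest adjusted p 0.696), and fry called 0 (smallest 0.0792). The immediate early list was not called by camera (adjusted p = 0.107). The medians were then 0.96 for antigen presentation, 0.51 for interferon, 0.72 for complement, 0.87 for phagocytic cells, 0.62 for lipid uptake, -0.59 for cholesterol synthesis, 0.35 for ribosomal proteins and 0.28 for immediate early genes. Leaving out 1 library ended 6 of the 9 camera calls. Cholesterol synthesis became 0.0805 and 0.121 without replicates 1 and 3 of SCI7, 0.0512 without replicate 2 of OVX2_SCI7 and 0.240 without replicate 4 of OVX8_SCI7. Lipid uptake became 0.216 without replicate 3 of SCI7, and 0.0554 and 0.121 without replicates 1 and 4 of OVX8_SCI7. Immediate early genes became 0.0518 without replicate 3 of SCI7 and 0.0823 without replicate 4 of OVX8_SCI7. Ribosomal proteins became 0.0876 without replicate 3 of SCI7 and 0.0683 without replicate 1 of OVX8_SCI7, complement 0.0584 without replicate 4 of OVX8_SCI7, and interferon 0.0527 without replicate 4 of SCI7. The phagocytic, antigen presentation and mitochondrial lists were called in 12 of 12 such fits. The number of lists called was 14 without replicate 2 of SCI7 or replicate 2 of OVX8_SCI7 and 5 without replicate 4 of OVX8_SCI7.

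Other named genes of the injury response and the hormone axis did not pass in OVX8_SCI7 against SCI7. Esr1 differed by -0.24 on the log2 scale and Pgr, the progesterone receptor gene, by -0.80 (SE 0.44), standing at 7.50 ± 1.34 against 13.1 ± 5.63 CPM. Gfap differed by 0.24, Mbp by 0.32, the neuronal gene Snap25 by -0.91 (SE 0.51) and Aif1, a marker of microglia and macrophages, by 0.92. Il1b, an inflammatory cytokine, differed by -0.18, Spp1, a macrophage and bone matrix protein, by 0.03 and Col1a1, fibrillar collagen, by 1.51 (SE 0.97). In OVX2_SCI7 against SCI7 the differences were -0.38 (SE 0.25) for Esr1, -0.56 for Pgr, 0.22 for Gfap, 0.41 for Mbp, -0.50 for Snap25 and 1.05 (SE 0.37) for Aif1. They were 0.83 for Il1b, -0.59 for Spp1 and 1.36 for Col1a1 there. The list of oestrogen and progesterone receptors and their responsive genes had medians of 0.39 and 0.24 in OVX2_SCI7 and OVX8_SCI7 (camera adjusted p = 0.844 and 0.561), with Igfbp4 higher and Nrip1 lower in OVX8_SCI7, both also when adjusted over the list alone, and the fitted change of Nrip1 was 0.04 under the GC and length offset.

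**Figure D3:**
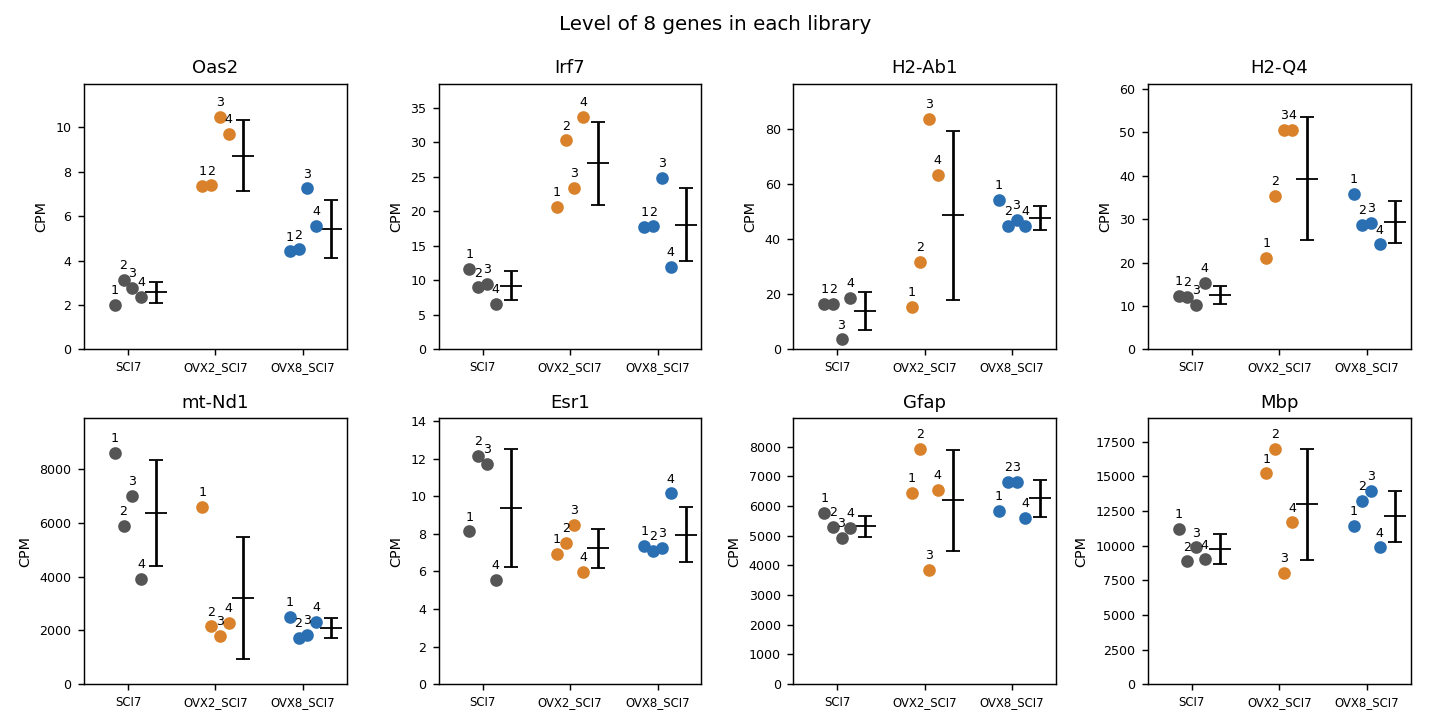
Counts-per-million (CPM) of 8 genes in each library, with the mean ± SD of the 4 libraries of each group. H2-Ab1 has means of 13.9 in SCI7, 48.7 in OVX2_SCI7 and 47.9 in OVX8_SCI7, and Oas2 has 2.57, 8.72 and 5.43.

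The third comparison sets 8 weeks against 2 weeks between ovariectomy and injury. No gene passed, and the 10 genes with the smallest p-values are given as values in order of p. Alox15 stood at 1.94 ± 0.604 CPM in OVX8_SCI7 and 0.412 ± 0.246 in OVX2_SCI7 (n = 4 per group), and Tsnaxip1 at 0.276 ± 0.0892 against 0.927 ± 0.112 CPM (log2 difference -1.70, SE 0.36). Alb, the albumin gene, stood at 1.55 ± 0.315 against 7.81 ± 6.26 CPM, Mapk15, a kinase, differed by -1.07 (SE 0.25), and Slc10a6, a transporter of steroid sulfates, stood at 0.431 ± 0.123 against 1.75 ± 0.911 CPM. Ttll6, an enzyme that modifies tubulin, the non-coding Etohd2, the ciliary genes Cfap206 and Dnah6, and Ccdc121rt1 differed by -0.89 (SE 0.22), -0.73 (SE 0.18), -0.95 (SE 0.25), -0.85 (SE 0.22) and -1.18 (SE 0.32). All 4 libraries of one group lay beyond all 4 of the other for each of these 10 genes, which were picked for a small p. The quasi-likelihood test of edgeR called 0 of 17821 genes, with a smallest Benjamini-Hochberg adjusted p of 0.999 and 393 genes at an unadjusted p under 0.05. DESeq2 called 3 genes, limma-voom 0, limma-voom with quality weights 1 and limma-trend on TPM 0, and edgeR called 1 gene without replicate 1 of OVX8_SCI7. With the GC and length offset edgeR called 0 genes and DESeq2 7, and without replicates 1 and 2 of OVX2_SCI7 edgeR called 0.

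Although no member of any list passed over all genes, limma camera called 16 of 50 lists in OVX8_SCI7 against OVX2_SCI7, 10 higher and 6 lower, and 0 with an estimated correlation. Skeletal muscle genes had a median log2 difference of 1.74 over 10 members (camera adjusted p = 2.2e-09). Myh4, a fast muscle myosin, stood at 5.82 ± 7.13 CPM against 0.620 ± 0.524, and its OVX8_SCI7 libraries held 16.2, 0.217, 2.30 and 4.59 CPM. Ckm, muscle creatine kinase, stood at 5.98 ± 5.89 against 0.608 ± 0.497 CPM. Cell division genes had a median of 0.57 over 19 members (camera adjusted p = 1.2e-08), with Mki67, a mark of proliferating cells, at 115 ± 25.7 against 60.8 ± 38.7 CPM. Fibrotic scar genes had a median of 0.45 over 19 members (camera adjusted p = 1.8e-07), with Postn, a scar matrix protein, at 284 ± 143 against 142 ± 164 CPM. With an estimated correlation the camera adjusted p was 0.406 for the muscle list and 0.732 for the cell division and fibrotic lists. Without replicates 1 and 2 of OVX2_SCI7, chosen after the data were seen, the camera direction of the cell division and fibrotic lists turned (adjusted p = 0.888 and 0.212).

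The interferon list had a median of -0.38 over 18 members and was called lower in OVX8_SCI7 by camera (adjusted p = 1.1e-06), but not with an estimated correlation (0.552) or by fry (0.908). Irf7 differed by -0.58 (SE 0.24). The ependymal list had a median of -0.53 over 8 members (camera adjusted p = 1.1e-06), with Dnah12, a dynein of cilia, lower when adjusted over the list alone (-1.07, SE 0.31). Immediate early genes had a median of 0.55 over 12 members (camera adjusted p = 5.9e-06), with Egr1 at 92.2 ± 23.7 against 52.0 ± 29.5 CPM. Cholesterol synthesis had a median of -0.37 over 21 members (camera adjusted p = 9.2e-06), with Idi1 differing by -0.83 (SE 0.42), and glucocorticoid-responsive genes one of -0.27 over 11 members (camera adjusted p = 0.00148), with Pdk4 differing by -0.54 (SE 0.18). Mitochondrially encoded transcripts had a median of -0.60 over 13 members (camera adjusted p = 4.9e-05) and one of -0.26 with the GC and length trend removed, which ended the call (camera adjusted p = 0.651). The camera adjusted p with an estimated correlation was 0.204 for ependymal, 0.485 for immediate early, 0.406 for glucocorticoid, and 0.732 for cholesterol and mitochondrial genes. In these lists 0 members passed over all genes, and Dnah12 was the only one that passed when adjusted over the list alone.

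Of the other 7 lists called there, all with 0 members passing over all genes or when adjusted over the list alone, 6 lay higher and 1 lower. The camera adjusted p was 0.000129 for matrix proteases (median 0.27), 0.00121 for phagocytic microglia and macrophages (0.22), 0.0013 for lipid uptake (0.14), 0.00648 for osteoclast and bone remodelling genes (0.22), 0.015 for B and plasma cells (0.29), 0.0161 for neutrophils (0.15) and 0.00758 for oligodendrocytes and myelin (-0.32). Mmp14, a membrane-bound collagenase, stood at 649 ± 126 CPM in OVX8_SCI7 and 341 ± 353 in OVX2_SCI7, and Lpl, lipoprotein lipase, at 527 ± 155 against 267 ± 235. Tnfrsf11a, the receptor that drives osteoclast formation, stood at 27.1 ± 3.23 against 19.6 ± 9.36 CPM, and Ugt8a, an enzyme of myelin lipid synthesis, at 175 ± 12.1 against 261 ± 143. Mpo, the neutrophil peroxidase, stood at 2.43 ± 1.33 against 0.912 ± 0.365 CPM and Igkc, the kappa light chain, at 2.24 ± 1.34 against 1.20 ± 0.788. With an estimated correlation the adjusted p of these 7 camera results was 0.432 for B and plasma cells, 0.736 for phagocytic cells, lipid uptake and myelin, and 0.732 for the 3 others. The fry test called 0 of the 50 lists, with a smallest adjusted p of 0.253.

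Leaving out 1 library ended 9 of the 16 camera calls. Without replicate 1 of OVX2_SCI7 the adjusted p was 0.641 for myelin and for lipid uptake, 0.607 for phagocytic cells, 0.120 for osteoclast genes and 0.308 for mitochondrial transcripts. Without replicate 2 of OVX2_SCI7 it was 0.30 for myelin, 0.199 for phagocytic cells, 0.464 for neutrophils, 0.347 for cholesterol, 0.329 for lipid uptake and 0.103 for osteoclast genes. Without replicate 3 of OVX2_SCI7 it was 0.266 for neutrophils, 0.327 for B and plasma cells and 0.0864 for glucocorticoid genes. Without replicates 2 and 3 of OVX8_SCI7 it was 0.201 and 0.0549 for neutrophils and without replicate 3 0.0583 for B and plasma cells, and without replicate 4 0.145 for myelin and 0.0872 for osteoclast genes. Without both replicates 1 and 2 of OVX2_SCI7, a choice made after the data were seen, camera called 23 lists and its direction turned in 18 lists called in either fit, among them 8 of the 16 lists above: cell division (adjusted p = 0.888), fibrotic scar (0.212), matrix proteases (0.455), phagocytic cells (0.0146), lipid uptake (0.00091), cholesterol (0.0014), osteoclast genes (0.833) and myelin (0.0822). The muscle, cell division, fibrotic, interferon, ependymal, matrix protease and immediate early lists were called in 12 of 12 fits that left out 1 library.

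Across the 3 groups together, the quasi-likelihood test of edgeR called 2654 of 17821 genes with Benjamini-Hochberg adjustment, and 6285 had an unadjusted p under 0.05. DESeq2 called 5047 genes and limma-voom 2547, and the GC and length offset left 0 in edgeR, with 1999 genes at an unadjusted p under 0.05 and 674 called by DESeq2. The edgeR count was 0 without any 1 of replicates 1, 2 and 3 of SCI7, replicate 4 of OVX2_SCI7 and replicates 2 and 3 of OVX8_SCI7. It was 1 without replicate 1 of OVX8_SCI7, 1628 without replicate 4 of SCI7 and 6054 without replicate 1 of OVX2_SCI7. With the replicate number as a block, a setting fixed beforehand, it was 0.

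The fitted differences of both ovariectomy groups from SCI7 had the same sign in most genes, although no gene passed in OVX2_SCI7 against SCI7. Slamf8, Lgals3bp and H2-Ab1 are examples, at 2.74 ± 0.920 and 2.51 ± 0.675, 263 ± 81.2 and 237 ± 21.5, and 48.7 ± 30.8 and 47.9 ± 4.38 CPM in OVX2_SCI7 and OVX8_SCI7, against 0.597 ± 0.166, 80.8 ± 21.1 and 13.9 ± 6.90 in SCI7. For H2-Ab1 replicate 1 of OVX2_SCI7, at 15.6 CPM, lay within the SCI7 range of 3.65 to 18.6. Across 17821 genes the covariance of the log2 fold changes of both comparisons was 0.486, with a correlation of 0.87 and the same sign in 89.6% of genes. The comparisons share the SCI7 libraries. In 20 simulations all libraries, SCI7 included, were drawn anew as unchanged groups. They gave a mean covariance of 0.0752 (highest 0.0812), a correlation of 0.501 and 66.7% of genes with the same sign. Genes were drawn independently and without a GC trend, so the range of these simulations may be too narrow for the real libraries. The difference of the covariances, 0.411, had a jackknife SE over libraries of 0.235, so it lies less than 2 SE from 0. With the SCI7 libraries split into pairs, each serving 1 comparison, the covariance was 0.460, 0.411 and 0.440 in the 3 splits, with a mean correlation of 0.672 and 80.5% of genes with the same sign. Under the GC and length offset the covariance was 0.259 with a correlation of 0.781. The overlap of called genes was 0, and so was the number that independent lists would share, because the first comparison called none.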

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

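The tests of ovariectomy against GC content, of both explanations for replicate 1 of OVX2_SCI7 and of both explanations for the sensory neuron transcripts were chosen after the result was seen, while the GC tests within gene lists and the counts over other splits of the libraries were planned before their results.

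The fold changes of OVX8_SCI7 against SCI7 followed transcript GC content, a pattern that GC bias in library making or sequencing could give and that a biological shift could also give. Within the fixed pathway lists, with each list's median removed, the Spearman correlation of fold change with GC content was 0.726 over 448 members (bootstrap interval 0.666 to 0.775), so the pattern is not made by whole pathways moving together, but a GC bias and a biological shift linked to GC content would both give this value. A different cell make-up moves the markers of 1 cell type together. Within marker lists, though, the correlation was 0.713 over 185 members (interval 0.623 to 0.790), which argues against cell make-up as the whole cause. Both bootstrap intervals resample genes, which are not independent, and hold no spread between animals. Ovariectomy itself stays open, since 8 of the 8 libraries from ovariectomised mice lay above every SCI7 library in this trend and the design confounds the group with any step done group by group. The margin was small for replicate 1 of OVX2_SCI7, at -0.44 against -0.53 for the highest SCI7 library. The other ovariectomised libraries lay at 0.18 to 0.87. A GC bias, a biological shift linked to GC content and ovariectomy cannot be told apart for the libraries here. Some non-coding entries also switched between SCI7 and OVX8_SCI7. Gm28439 held 200.2 to 4775 CPM in SCI7 and 0 in every OVX8_SCI7 library, and Gm43118 held 0 and 3.67 to 7.58 CPM. They were picked for parting these libraries, so they do not decide between a processing step and ovariectomy.

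Replicate 1 of OVX2_SCI7 lay with the SCI7 libraries rather than with its own group in several measures, but not in all. On the 200 genes that best part OVX8_SCI7 from SCI7 after GC adjustment, with SCI7 at 0 and OVX8_SCI7 at 1, it stood at 0.0898, inside the range of the held-out SCI7 libraries (-0.0656 to 0.278) and below the other OVX2_SCI7 libraries (0.864 to 1.07), as a wrong label or a swap with a sample outside the groups could give. Of 15 non-coding and pseudogene entries that switched on or off between SCI7 and the other 7 libraries, 86.7% were on the SCI7 side in it, against 0 to 6.25% of 15 or 16 entries picked anew in the same way for each other OVX2_SCI7 library with replicate 1 left aside, which fits a library or processing batch shared with SCI7 as well. Gm28439, for example, held 200.2 to 4775 CPM in SCI7, 1045 in this library and 0 in the other 7. Both explanations stay open, and Oas2 at 7.37 CPM and Cd8a at 0.795 CPM lay above every SCI7 library in it, although these genes were chosen with this library in its group. A list score is the mean log2 CPM deviation of a list's members. Its scores were 0.148 for interferon, 0.413 for ependymal and 0.254 for glucocorticoid genes, where the highest SCI7 scores were -0.0111, -0.00655 and -0.105. For antigen presentation, complement, ribosomal and mitochondrial genes it lay within the SCI7 range. These lists were called with this library in its group.

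Replicate 2 of OVX2_SCI7 held transcripts of sensory neurons, which have their cell bodies in the dorsal root ganglia beside the cord. Of 14 detected ganglion markers 92.9% were higher in it than in each of the 11 other libraries, with Pirt at 135 CPM, Sncg at 152 and Scn11a at 54.9, which ganglion tissue in the sample could explain. More spared spinal neurons are argued against, because the median ratio to the other libraries was 22.1 for ganglion markers and 1.65 for the neuron list, 13.4 times as large. Pirt stood at 7.16 to 21.6 CPM in replicates 2 and 3 of SCI7, replicate 3 of OVX2_SCI7 and replicate 2 of OVX8_SCI7. No group of the design goes with this pattern, so no other biological explanation was tested.

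A library stood apart from the 3 others of its group, by the ratio of its gap to the group's range, in 3 of 12 groups of library measures, 6 of 150 list scores and 23 of 417 groups of named genes, where chance gives about 1 in 20 groups (0.6, 7.5 and 20.85). For replicate 1 of OVX2_SCI7 the ratio was 0.87 for the mitochondrial share (8.33% against 2.36 to 3.13%), 0.861 for the GC trend (-0.44 against 0.41 to 0.54) and 0.888 for the mitochondrial list score. It was 0.935 for mt-Nd6, 0.899 for mt-Nd1, 0.916 for mt-Nd4, 0.86 for mt-Nd3, 0.897 for Rpl37rt and 0.861 for Or8b48, and 1 for H3c14 and Snurf, at 4.24 and 2.60 CPM where the 3 others were at 0. The list scores of replicate 3 of SCI7 were low for phagocytic microglia and macrophages (0.905), antigen presentation (0.906), lipid uptake (0.837), osteoclast genes (0.868) and lysosome genes (0.876), as were its CPM of Lgals3bp (0.927, 49.2 against 89.3 to 92.4) and H2-Ab1 (0.868, 3.65 against 16.7 to 18.6). For replicate 2 of OVX2_SCI7 the ratio was 0.862 for the library total (20371555 counts against 19223185 to 19381740.0) and 0.833 for Dynlrb2. Other ratios in OVX2_SCI7 were 0.873 for Cd8a and 0.941 for Il1b in replicate 3 (Il1b at 5.41 against 0.674 to 0.954 CPM), and 0.94 for Igkc in replicate 4. In OVX8_SCI7 they were 0.846 for H2-D1 and 0.833 for Aif1 in replicate 1, 0.987 for Igkc and 0.85 for Ighm in replicate 3, and 0.908 for Esr1, 0.909 for Retnlg, 0.86 for Tgfbr2 and 1 for H3c14 in replicate 4. Replicate 1 of SCI7 had 0 CPM of Rsc1a1 against 2.10 to 2.40 in the others (ratio 0.873).

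Between OVX8_SCI7 and OVX2_SCI7, with ovariectomy 8 and 2 weeks before the injury, limma camera called a difference in 16 gene lists. Its adjusted p was 2.18e-09 for skeletal muscle, 1.16e-08 for cell division, 1.77e-07 for fibrotic scar matrix, 5.92e-06 for immediate early genes, 0.000129 for matrix proteases, 0.00121 for phagocytic microglia and macrophages, 0.0013 for lipid uptake, 0.00648 for osteoclast genes, 0.015 for B and plasma cells and 0.0161 for neutrophils, all higher in OVX8_SCI7. It was 1.13e-06 for ependymal cells and for type I interferon, 9.16e-06 for cholesterol synthesis, 4.92e-05 for mitochondrially encoded transcripts, 0.00148 for glucocorticoid-responsive genes and 0.00758 for oligodendrocytes, all lower in OVX8_SCI7, and 0 of the 16 passed with an estimated correlation or in fry. Without replicates 1 and 2 of OVX2_SCI7, a choice made after the data were seen, 8 of the 16 changed direction: cell division (0.888), fibrotic scar (0.212), matrix proteases (0.455), phagocytic cells (0.0146), lipid uptake (0.00091), cholesterol (0.0014), osteoclast genes (0.833) and oligodendrocytes (0.0822). As many lists were called in 19 of 35 splits of the libraries.

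Other splits of the same libraries into groups of the same sizes were used to see whether chance can be excluded. For OVX8_SCI7 against SCI7 the real split was the only 1 of 35 with 4894 genes, the highest other giving 0. This argues against chance for that count but does not firmly exclude it. A share of 1 in 35 is the smallest these splits allow and is not adjusted over the counts tested. The count was also 0 without replicate 2 of OVX8_SCI7. For the 3 groups together 4 of 100 drawn splits gave as many as the real 2654 genes, the highest other 7274. That share is just under 1 in 20 and comes from drawn splits, so its error spans that limit and chance is not firmly excluded. Of the splits that gave more genes, those with 3919 and 3444 kept the 4 SCI7 libraries together and mixed only the ovariectomy groups. The split with 7274 set replicate 1 of OVX2_SCI7 with replicates 1, 2 and 3 of SCI7, a structure of the samples that crosses the labels. For OVX2_SCI7 against SCI7 and OVX8_SCI7 against OVX2_SCI7 the real count was 0, which all 35 splits must reach, so the number of splits says nothing about chance there. Setting replicate 1 of OVX2_SCI7 with replicates 1, 2 and 3 of SCI7 gave 5884 genes in the first of these, a structure of the samples that crosses the labels, and the highest other count in the second was 0. Chance is not excluded for the number of lists called, since 34, 29 and 19 of 35 splits gave as many as the real 7, 9 and 16, with 30, 28 and 30 lists in the highest other split.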

How the results depend on the processing

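The tests with the GC and length offset, with protein-coding nuclear genes only and without both replicates 1 and 2 of OVX2_SCI7 were chosen after the data were seen, and all other settings were fixed before. Among the settings fixed beforehand 110 counts and shared-change values stayed within 1.5 times or the spread and 50 moved. Of the named genes' values 6289 kept their direction and side of the threshold, 419 fell below it, 305 rose past it and 36 without a call moved, and 0 called ones changed sign. Single lists kept their call or its absence in 2469 cases, lost it in 110, gained it in 109, moved in 160 and turned in 2. Among the added settings 12 counts stayed and 25 moved, and of the named genes' values 291 stayed, 85 fell below the threshold, 5 rose past it, 25 moved and 9 turned, while single lists stayed in 368 cases, moved in 97, lost their call in 71, gained it in 46 and turned in 18. The cause was not tested unless stated. Depth limits low genes, since 3 counts equal 0.0944 to 0.165 CPM.

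For OVX2_SCI7 against SCI7, where edgeR called 0 genes, the count was 14 with no filter, 1148 with the strict filter, 3579 by DESeq2, 705 by limma-voom, 9679 with quality weights, 16 by limma-trend on TPM, 2 from 8 libraries, 8 with the GC offset, 433 by DESeq2 with the offset, 720.0 on protein-coding nuclear genes, 7139 without replicates 1 and 2 of OVX2_SCI7, 1631 with the offset as well, and 0 to 6264 on leaving out 1 library, where removal of replicate 1 of OVX2_SCI7 gave the highest. For OVX8_SCI7 against SCI7 (4894 genes) it was 1493 with a log2 fold change of at least 1, 3252 with no filter, 11212 with quality weights, 2878 by limma-trend, 7424 from 8 libraries, 0 with the offset, 824 by DESeq2 with it, 7720.0 without the 2 doubted libraries, 773 with the offset as well, and 0 to 6706 on leaving out 1 library, with 0 without replicate 2 of OVX8_SCI7. For OVX8_SCI7 against OVX2_SCI7 (0 genes) it was 3 by DESeq2, 1 with quality weights, 7 by DESeq2 with the offset and 0 to 1 on leaving out 1 library. Across the 3 groups (2654 genes) it was 1372 with no filter, 5047 by DESeq2, 11436 with quality weights, 744 by limma-trend, 0 with the offset, 674 by DESeq2 with it, 7573 without the doubted libraries, 1110.0 with the offset as well, and 0 to 6054 on leaving out 1 library.

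The number of lists called in OVX2_SCI7 against SCI7 (7) was 15 with no filter, 0 with an estimated correlation, 3 by fry, 15 with the GC trend removed, then 0 with an estimated correlation and 2 by fry, 19 without the doubted libraries and 6 to 11 on leaving out 1 library. In OVX8_SCI7 against SCI7 (9) it was 17 with no filter, 0 with an estimated correlation, 0 by fry, 16 with the GC trend removed, then 0 and 0, and 5 to 14 on leaving out 1 library. In OVX8_SCI7 against OVX2_SCI7 (16) it was 0 with an estimated correlation and 0 by fry, with the GC trend removed or not, and 12 to 23 on leaving out 1 library. The covariance of the shared change, 0.486, was 0.438 to 0.705 on leaving out 1 library.

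Turned results were these. Without replicates 1 and 2 of OVX2_SCI7, camera turned 18 lists of OVX8_SCI7 against OVX2_SCI7 that were called in either fit, with adjusted p of 5.91e-06 for neurons, 0.00814 for cholinergic motor neurons and for apoptosis, 0.00218 for astrocytes, 0.0822 for oligodendrocytes, 0.0146 for phagocytic microglia and macrophages, 0.000766 for monocytes, 0.0014 for cholesterol synthesis, 0.00091 for lipid uptake, 0.00184 for inflammasome, 0.049 for complement, 2.49e-07 for antigen presentation, 0.212 for fibrotic scar, 0.455 for matrix proteases, 0.833 for osteoclast genes, 0.888 for cell division, 0.0214 for senescence and 3.32e-12 for ribosomal proteins. Without replicate 1 of OVX2_SCI7 alone, antigen presentation and ribosomal proteins turned, and on leaving out 1 library their adjusted p ran from 0.000402 to 0.923 and from 0.00201 to 0.663, the lowest without that replicate. Over all alternatives the adjusted p of these 18 lists ran from 6e-15 to 0.998. Under the GC offset 9 named genes called in OVX8_SCI7 against SCI7 changed sign, because the offset removes each library's GC trend: Foxj1 (-0.17), Nrip1 (0.036), Akr1c14 (0.11), Hcn2 (-0.086), Phlda3 (-0.055), Hmgb1 (0.25), Herpud1 (-0.026), Uqcrc1 (-0.19) and Tfeb (-0.045).

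The replicate numbers do not pair the samples, since 5 of 12 same-numbered pairs of libraries correlated over 0.1 in their deviations (-0.626 to 0.50) and 4 libraries correlated best with their own number. With the number as a block, edgeR called 0 genes for OVX2_SCI7 against SCI7, 3390.0 for OVX8_SCI7 against SCI7, 0 for OVX8_SCI7 against OVX2_SCI7 and 0 across the 3 groups, and with the GC offset as well 0, 1, 0 and 0. The block without the offset ended the calls of 32 of the 94 named genes that passed in OVX8_SCI7 against SCI7, with 0 changes of sign.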

Other observations

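The tests in this part were planned, except that members named outside the rule were chosen after their values were seen.

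Several cell type and pathway lists that camera did not call in OVX8_SCI7 against SCI7 still held genes that passed the quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment. Among markers of homeostatic microglia, Selplg and Tmem119 rose while the purinergic receptors P2ry12 and P2ry13 and Gpr34 fell, and the list's median log2 fold change was 0.06 (camera adjusted p = 0.681). Among B and plasma cell genes, Cd79b, Ighm and Igkc rose, 3 of 5 tested members, with a median of 1.03 (camera adjusted p = 0.0574). Among myelin genes, Aspa, Ermn and Ugt8a fell, 3 of 12, with a median of -0.48 (camera adjusted p = 0.207). In the list of oxidative stress and ferroptosis, Gpx4, the enzyme that detoxifies lipid peroxides, rose while Slc7a11, Gclc and Gclm, which supply glutathione, and Acsl4 and Tfrc fell (median -0.09, camera adjusted p = 0.305). In the skeletal muscle list Myh4 and Tnni2 rose, with a median of 1.82 (camera adjusted p = 0.061). The libraries varied widely in this list. Replicate 2 of OVX8_SCI7 had a list score of -1.22, within the SCI7 range of -1.85 to 0.199, while the other OVX8_SCI7 libraries were at 1.38 to 2.28. When adjusted over the list alone, the members higher and lower were 3 and 3 for homeostatic microglia, 3 and 0 for B and plasma cells, 0 and 3 for myelin, 1 and 6 for oxidative stress and 0 and 0 for muscle, and with the GC and length offset, chosen after the data were seen, none of these genes passed.

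Clock and stress genes moved both ways in the same comparison. Dbp and Per1 rose while Clock and Nr1d2 fell, 4 of 15 circadian genes with a median log2 fold change of 0.06 (camera adjusted p = 0.939). The heat shock genes Hspa1a and Bag3 rose and the mitochondrial chaperone gene Hspd1 fell, 3 of 10 (median 0.20, camera adjusted p = 0.561). The growth-associated transcription factor gene Jun rose while Sox11 and Klf7 fell, 3 of 16 genes of axon growth (median 0.05, camera adjusted p = 0.891). Markers of neurons had a median of -0.59 (0 of 12 passing, camera adjusted p = 0.806) and those of bone and cartilage 0.14 (0 of 8 passing, camera adjusted p = 0.807). Adjusted over the list alone, the members higher and lower were 2 and 2 for the clock, 4 and 1 for heat shock, 1 and 2 for axon growth, and 0 and 0 for neurons and for bone and cartilage. The camera adjusted p with an estimated correlation was 0.978 for the circadian list and 0.970 for the other lists of this part. With the GC and length offset, chosen after the data were seen, edgeR called none of the genes named in this paragraph. The medians were then -0.25 for the clock, -0.076 for heat shock, -0.20 for axon growth, -0.40 for neurons and -0.15 for bone and cartilage.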
